A study of Mus musculus with 36 samples.

How the data were processed

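The series holds 36 samples of mouse testis, per the labels: 18 RNA-seq libraries of wild-type and D1Pas1 knockout testes (3 per genotype at P14, P18 and P28), 6 small RNA libraries (3 per genotype, made from oxidised RNA, which enriches for piRNAs), 6 eCLIP libraries from knock-in testes (3 precipitates and 3 size-matched inputs) and 6 BisMapR libraries. The BisMapR samples were not analysed here. The labels give male germ cell as the cell type, and no age for the small RNA and eCLIP samples. Groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, and what was chosen later is named where it is used.

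The RNA-seq values are estimated counts per gene, which the authors deposited unscaled in 1 table per age, each with 24626 genes. Per the submitters' processing notes, reads were trimmed with cutadapt 3.4 and build mm10 was used. The names of the deposited tables speak of estimated counts and of a step from transcripts to genes, while the aligner and annotation are not given in the sources used here. Between 74.8% and 81.8% of the listed values per library were not whole numbers. The small RNA values are a signal per piRNA cluster transcript that the authors normalized before they deposited it, by a method that is named but not defined in the sources used here. Each table has 2 value columns without a header, and the first was used for the comparisons. The eCLIP values are counts of cross-link events in sliding windows of up to 50 nt along exons and introns, as deposited by the authors without scaling. For small RNA and eCLIP the submitters' processing notes name cutadapt 3.4, HTSeq without a version, and mm10.

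Estimated counts were rounded to whole numbers and tested per age with edgeR 4.0.16 in R 4.3.3 (trimmed-mean scaling factors, TMM; low-count filter of the package by genotype; two-sided quasi-likelihood F-test on genotype). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 for every call in the text. Values per library are counts scaled to library size (CPM). Whether the genotype effect differs between neighbouring ages was tested as the interaction of age and genotype over the 12 libraries of 2 ages. Otherwise ages were compared only in the closing section, as the change of wild-type libraries from P14 to P28 by the same test. Each age has its own table and may be its own batch. Overlaps of calls between ages were set beside the number that independent lists would share. Where all knockout libraries had 0 counts, the fold is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with a 95% interval. Such intervals cover counting error only.

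Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2, preset correlation between genes of 0.01, at least 5 tested members, two-sided). The adjustment ran over all lists at all ages. Camera with an estimated correlation was run beside it. There were 23 fixed lists: DDX3 relatives, piRNA pathway, synapsis and recombination, pachytene spermatocyte, meiotic division, round spermatid, elongating spermatid, axoneme, spermatogonial, Sertoli, Leydig, peritubular, macrophage and immune, endothelial, red blood cell, p53 targets, DNA repair, R-loop processing, sex-linked genes silenced at pachytene, post-meiotic sex-linked genes, interferon response, translation factors and cytosolic ribosomal proteins. All tested X-linked and Y-linked genes made 25 lists. Of the listed genes, 32 of 34 were matched for the piRNA pathway, 50 of 54 for synapsis, 43 of 46 for the axoneme, 10 of 11 for red blood cells and 25 of 26 for post-meiotic sex-linked genes, and every gene of the other fixed lists. The DDX3 list has 4 genes, too few for camera, and its genes are given singly. On the sex chromosomes 967 X-linked and 46 Y-linked genes were matched. Several lists share members, such as Ccna1, Aurkc and Tcp11. The somatic cell types of these lists are part of the testis, so their transcripts belong to the tissue.

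Genes are named by a fixed rule. At each age these are D1Pas1, Ddx3x and Ddx3y. To them come the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 1 and every knockout library beyond every wild-type library, where predicted or clone-named models are only counted. From each list described, up to 4 members with the smallest p-value are named, with a few stage and cell markers chosen in advance. For piRNA clusters the rule takes the 5 most abundant in wild type, the 5 largest falls, the 5 largest rises and 9 clusters chosen by name. For eCLIP it takes the 10 largest enrichments present in every precipitate, and the 3 helicase genes.

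Each small RNA cluster took the value of 1 listed transcript, the one with the highest mean over all libraries. Clusters are genic where their name is that of a gene and intergenic where it is a chromosome band. Log2 of the value plus 1 was tested per cluster with limma (two-sided moderated t-test with a mean-variance trend, clusters with a mean of at least 1). Totals per library were compared by exact two-sided permutation of the 20 assignments of 3 against 3 samples, for which the smallest p is 0.1.

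Neighbouring eCLIP windows overlap, so that 1 event is listed more than once. Of isolated runs of windows with single events, 95.1% to 97.4% per library spanned 2 or 3 windows. Therefore 1 window in 3 was used and its counts were summed per gene or piRNA cluster, giving 42692 features from 42477 Ensembl identifiers and 215 clusters. Of the identifiers 173 had no symbol. Enrichment of precipitates over inputs was tested with edgeR as above. Depth was low in the precipitates: 49.0% of these features had 0 counts in precipitate 1. Gene positions come from a reference gene table of GRCm38. No genome sequence was used.

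The procedures were tested on simulated data drawn from the means and library sizes of the real genes, with 200 genes changed by known folds, or 40 clusters. At a 2-fold change, edgeR recovered 84% of changed genes at P14, 70% at P18 and 11% at P28, and at a 4-fold change 96%, 95% and 68%. For the interactions it recovered 54% and 5% at 2-fold and 82% and 57% at 4-fold, for eCLIP 28% and 93%, and limma recovered 60% and 70% of clusters. False calls made up 3.97% to 10.3% of calls by edgeR and limma. For DESeq2 they made up 16.4%, 16.7% and 36.0% at P14, P18 and P28. These shares of false calls need not hold for the real calls. Simulated genes and clusters varied independently of each other, while real clusters shared a pattern of differences between libraries. Only 200 simulated genes were changed, while 56.3% of tested genes were called in the real data at P28. The spread of the simulated counts was estimated without the TMM factors that the real fits use. The recovered shares of count data therefore need not equal the power of those fits, above all at P28, where wild-type factors ran from 0.70 to 0.96.

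Alternatives fixed in advance were DESeq2 1.42.0, relative log expression factors (RLE), library totals alone, no low-count filter, a 2-fold minimum, 1 fit of all 18 RNA-seq libraries, each library left out in turn, replicate numbers as a block, other pseudocounts (0.1 and 10), each small RNA library scaled to the same total, and the small RNA total without its 5 most abundant clusters. Chosen after seeing the data were every small RNA transcript as its own unit, the 2 other sets of eCLIP windows, exon windows alone and intron windows alone. Each result was also recomputed for other splits of the same samples into groups of 3, all 10 splits per comparison, and 40 drawn of 200 for each interaction. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.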

Results

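Gene expression was measured by RNA-seq in testes of wild-type and D1Pas1 knockout mice at postnatal days 14, 18 and 28 (P14, P18 and P28), with 3 libraries per genotype and age. D1PAS1 is a DEAD-box RNA helicase of germ cells, encoded by a gene closely related to the X-linked Ddx3x and the Y-linked Ddx3y. Small RNAs, treated so that piRNAs are enriched, were sequenced from 3 wild-type and 3 knockout samples of unstated age. RNA bound by D1PAS1 was profiled by eCLIP, in which UV cross-linked protein is precipitated with its RNA, in 3 precipitates (IP) and 3 size-matched inputs from knock-in testes. The 6 samples of an R-loop assay (BisMapR) were not analysed here. Estimated counts per RNA-seq library ran from 21.8 to 30.4 M at P14, from 16 to 21.7 M at P18 and from 23.7 to 40.9 M at P28. The labels do not state that samples come from separate animals, so all p-values measure the spread between these samples.

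D1Pas1 itself (chromosome 1, 186967416 to 186970627, GRCm38) was lower in knockout libraries at every age. At P14 it lay at 37.8 ± 6.86 CPM (counts scaled to library size) in wild type and 15.6 ± 1.73 in knockout (mean ± SD, n = 3 per group, as for all values of this kind). The values were 88.1 ± 35.5 against 19.9 ± 4.18 at P18, and 255 ± 95 against 38.0 ± 6.42 at P28. Every knockout library lay below every wild-type library at each age. By edgeR the log2 fold change was -1.28 ± 0.14 (SE; adjusted p = 0.0860) at P14, -2.14 ± 0.29 (adjusted p = 9.74e-04) at P18 and -2.74 ± 0.31 (adjusted p = 1.81e-04) at P28. At P14 the change passed the threshold by DESeq2 (adjusted p = 2.14e-15), without the low-count filter (adjusted p = 0.0336) and without wild-type library 2 (log2 fold change -1.13, adjusted p = 0.0164). The size of the loss did not differ detectably between neighbouring ages, by -0.87 from P14 to P18 (adjusted p = 0.148) and by -0.74 from P18 to P28 (adjusted p = 0.235), and P14 was not tested against P28.

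The paralogs Ddx3x and Ddx3y, which encode closely related helicases, were higher in the knockout at P28. Ddx3x rose from 123 ± 34.2 to 297 ± 28.7 CPM (log2 fold change 1.27 ± 0.23, adjusted p = 0.00250) and Ddx3y from 40.5 ± 14.8 to 107 ± 13.3 (1.40 ± 0.27, adjusted p = 0.00307). At P14 their log2 fold changes were 0.04 and -0.02, and at P18 they were 0.26 (adjusted p = 0.244) and 0.31 (adjusted p = 0.1). Ddx3x at P18 passed the threshold without wild-type library 9 (0.40, adjusted p = 0.0388), and Ddx3y at P18 passed it with library totals alone (0.43, adjusted p = 0.0283). The increase in fold change from P18 to P28 was itself called for Ddx3x (0.86, adjusted p = 0.0440) and Ddx3y (0.94, adjusted p = 0.0456). Both belong to the list of sex-linked genes silenced at pachytene, which had a median of 0.90 at P28, with 25 of 35 genes higher and 1 lower. No test compared the 2 paralogs with that list. Ddx4, the germ-cell helicase VASA and the other member of the family list, had values of -0.03 at P14, -0.39 at P18 (adjusted p = 0.0444) and -0.72 at P28 (adjusted p = 0.0153). With library totals alone Ddx4 stood at -0.27 (adjusted p = 0.0969) and -0.16 (adjusted p = 0.289) at P18 and P28. Ddx4 at P28 had an adjusted p of 0.0533 or 0.0570 without knockout library 4 or 5, and Ddx4 at P18 of 0.0509 to 0.182 without any library other than wild type 9. How reads shared between these near-identical genes were divided is not given in the sources used here.

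**Figure D1:**
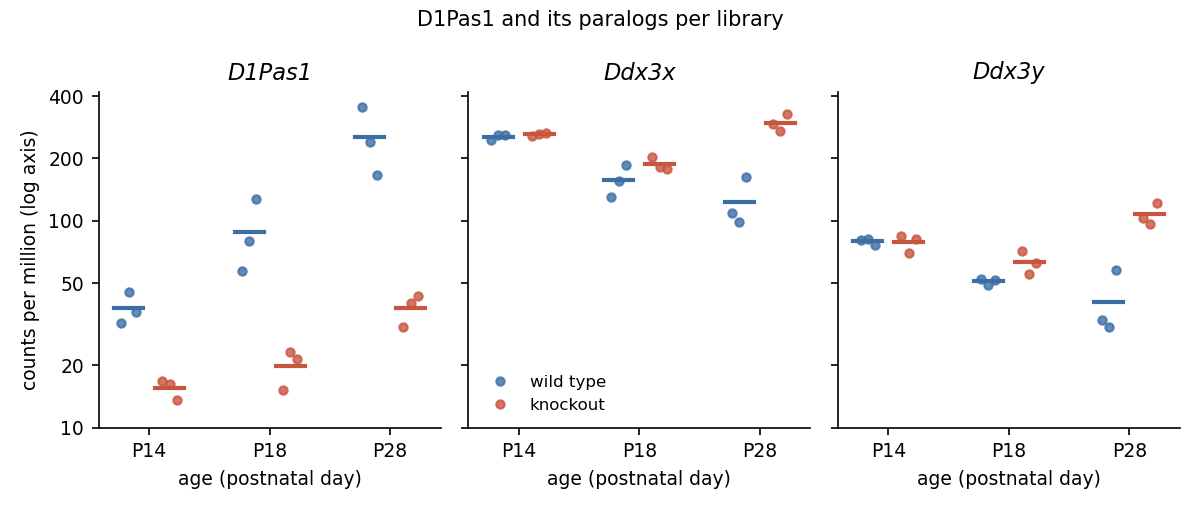
CPM (log axis) of D1Pas1, Ddx3x and Ddx3y in each library (points) with group means (bars) at P14, P18 and P28. D1Pas1 fell to a mean of 38.0 CPM in the P28 knockout, against 255 in wild type, while Ddx3x and Ddx3y stood higher there.

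The P14 comparison asked whether the knockout testis already differs before the later stages of meiosis. D1Pas1 was lower, and of 3 markers of germ-cell stages Stra8, a regulator of meiotic entry, had a log2 fold change of -0.05, Sycp3, of the synaptonemal complex, -0.06, and Piwil1, which encodes a piRNA-binding protein, -0.19. Some genes of later stages stood lower without being called: Adam3 at -1.57 (adjusted p = 0.762), Ldhc at -0.67 (0.816), Spata16 at -0.56 (0.884) and Acr at -0.53 (0.866). The pachytene and round spermatid lists had medians of -0.11 and -0.17 and were not called (camera adjusted p = 0.115 and 0.0641). The direction depended on wild-type library 2. Without it the pachytene and elongating spermatid lists were called higher. The largest departure of a gene list was that of the 39 tested axoneme and ciliary genes, with a median of -0.27 (quartiles -0.45 to -0.10). Among them the radial spoke gene Rsph6a stood at -1.28 (adjusted p = 0.634) and the dynein heavy chain gene Dnah17 at -1.11 (adjusted p = 0.735). Markers of peritubular myoid and smooth muscle cells had a median of 0.20 over 22 genes, and endothelial markers of 0.15 over 16 genes. Myh11, a smooth muscle myosin, stood at 0.32 (adjusted p = 0.330) and Dcn, which encodes decorin, at 0.23 (adjusted p = 0.444). Adjusted over the list alone, 5 peritubular markers and 1 Leydig cell marker were higher.

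Of 15922 genes tested at P14, edgeR called 0. At an unadjusted p under 0.05 there were 948 genes, where 796 are expected by chance, and DESeq2 called 48 higher and 10 lower. Without the low-count filter edgeR called 4, and without wild-type library 2 or 3 it called 11 or 5. Groups did not overlap for 11.3% of genes, where chance gives 10%. By camera 5 lists differed from the other genes, with no tested member called over all genes. These were the axoneme list (lower, adjusted p = 1.37e-05; 0.660 as the adjusted p with an estimated correlation), peritubular markers (higher, 9.18e-08; 0.503), endothelial markers (higher, 1.10e-04; 0.503), p53 targets (median 0.07, 0.0128; 0.584) and X-linked genes (median 0.03, 0.0442; 0.660). Without wild-type library 2 the adjusted p was 0.87 for the axoneme list, 0.0903 for p53 targets and 0.951 for X-linked genes. The list p53 targets, DNA damage and apoptosis at P14 was also not called without knockout library 5 (0.278), nor were X-linked genes without knockout library 4 (0.0647), 5 (0.0601) or 6 (0.142).

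At P18, when wild-type testes hold many pachytene spermatocytes, genes of late meiosis, of the sperm tail and of early spermatids were lower in the knockout, and genes of the X and Y chromosomes were higher. The axoneme and ciliary list changed most: of 42 tested genes 38 fell and none rose (39 fell adjusted over the list alone), with a median log2 fold change of -2.20 (quartiles -2.90 to -1.70). Tekt3, a tektin of flagellar microtubules, fell from 24.1 ± 7.43 to 0.0701 ± 0.0282 CPM, Rsph6a by 5.99 on the log2 scale, Cfap70 by 3.93 and Dnaaf1, needed for dynein assembly, by 2.94. Among 37 pachytene spermatocyte genes 29 fell and 2 rose (30 and 2 adjusted over the list alone), with a median of -1.29 (quartiles -2.25 to -0.52). Adam3, a sperm surface protein gene, fell by 5.21, the transcription factor Pou5f2 by 5.76, Spata16 by 3.77, and Ldhc, the testis lactate dehydrogenase, from 966 ± 124 to 162 ± 29.6 CPM (adjusted p = 2.73e-05). The adjusted p of the camera test was 1.26e-22 for the axoneme list and 1.13e-12 for the pachytene list. Both had an adjusted p = 0.503 with an estimated correlation.

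Genes of the meiotic divisions and of spermatids were lower as well. Of 35 meiotic division genes 14 fell and 1 rose (20 and 2 adjusted over the list alone). Ccna1, the germ-cell cyclin A, fell from 28.9 ± 13.7 to 1.45 ± 0.276 CPM (log2 fold change -4.30 ± 0.41, adjusted p = 1.48e-04), and Aurkc, a meiotic aurora kinase, fell by 2.25. Hspa2, a chaperone of late meiotic prophase, fell from 980 ± 162 to 535 ± 43.0 CPM (-0.87, adjusted p = 0.00283). Of 22 round spermatid genes 16 fell and none rose (17 adjusted over the list alone; median -1.52), among them the acrosomal genes Acr (-2.45) and Acrbp (-2.92). Of 20 elongating spermatid genes 13 fell and none rose (14 adjusted over the list alone; median -1.12), among them Tcp11 (-3.49) and the outer dense fibre gene Odf4 (-2.11). The camera adjusted p was 0.00296 for the division list (median -0.32), 1.68e-08 for round and 6.16e-06 for elongating spermatid genes. With an estimated correlation each had an adjusted p = 0.503.

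Genes for piRNA pathway proteins were lower at P18. Of 32 tested 13 fell and none rose (16 and 1 adjusted over the list alone), with a median of -0.27, an adjusted p = 6.81e-04 by camera and an adjusted p = 0.503 with an estimated correlation. Tdrd6, a tudor-domain protein of the chromatoid body, fell from 295 ± 34.7 to 38.5 ± 14.8 CPM. Henmt1, which methylates piRNA ends, fell by 1.46 on the log2 scale, Pld6 by 1.41, Gtsf1 by 1.05 and Piwil1 by 1.21 (adjusted p = 0.00284). Mybl1, the transcription factor of pachytene piRNA precursors, had a log2 fold change of -0.16 (adjusted p = 0.369). Synapsis and recombination genes, which act earlier in meiotic prophase, had a median of -0.08: of 50 tested 11 fell and 1 rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.497). Syce1 fell by 1.21, and Sycp3 stood at -0.16 (adjusted p = 0.560).

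Sex-linked genes stood mostly above wild type at P18, though most were not called singly. Of 593 tested X-linked genes 90 rose and 1 fell (73 and 1 adjusted over the list alone), with a median of 0.27 (quartiles 0.16 to 0.39; camera adjusted p = 3.05e-17, but 0.194 with an estimated correlation). Of 17 Y-linked genes 7 rose and none fell, also adjusted over the list alone (median 0.75; camera adjusted p = 2.93e-06, but 0.503 with an estimated correlation). In the list of sex-linked genes that are normally silenced at pachytene, 18 of 34 rose and none fell (22 adjusted over the list alone; median 0.35, camera adjusted p = 2.34e-10, but 0.194 with an estimated correlation). Zfy1 and Zfy2, Y-linked zinc finger genes whose expression at pachytene is harmful to spermatocytes, rose from 11.4 ± 2.14 to 24.1 ± 4.95 and from 12.6 ± 3.63 to 32.8 ± 7.39 CPM (adjusted p = 0.00603 and 0.00481). The Y-linked deubiquitinase gene Usp9y rose by 0.67 and the X-linked Tex16 by 0.55. Of 9 tested post-meiotic sex-chromosome genes none rose and 1 fell (median 0.24, mean -0.67, camera adjusted p = 0.606). The member that fell, Ccdc7b, lies on chromosome 8.

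Markers of somatic cells and spermatogonia stood slightly higher in the same libraries. The medians were 0.21 for 36 Sertoli cell markers (2 rose, 1 adjusted over the list alone; camera adjusted p = 6.81e-04), 0.21 for 23 Leydig cell markers (2 rose, 1 adjusted over the list alone; 0.0125) and 0.22 for 35 spermatogonial genes (0.00730). With an estimated correlation the adjusted p = 0.503 for Sertoli markers, 0.658 for Leydig markers and 0.503 for spermatogonial genes. Shbg, of Sertoli cells, rose from 72.1 ± 3.31 to 138 ± 33.9 CPM. Among spermatogonial genes 2 rose and 2 fell (0 and 2 adjusted over the list alone), with Dmrtb1, a regulator of the switch from mitosis to meiosis, falling by 1.59 and Id4 by 0.72. Without knockout library 10 the Leydig list was not called (adjusted p = 0.141). Peritubular, macrophage and endothelial markers had medians of -0.05, 0.10 and 0.12 over 22, 23 and 16 genes (camera adjusted p = 0.819, 0.219 and 0.201). Of these, Igf1 rose (0.50) and Fcgr3, a macrophage receptor, fell (-1.04).

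Over all 15722 genes tested at P18, edgeR called 502 higher and 2365 lower, or 18.2%, with 66 and 1312 of them changed at least 2-fold. DESeq2 called 878 higher and 2493 lower, and 2802 genes were called by both tools. Among the largest rises, leaving out predicted gene models, were those of Fam181b (4.95 ± 0.37), the ribosomal pseudogene Rps15a-ps6 (3.86), Pcbd1 (2.73), Serpina3a (2.42), the X-linked Prame (2.30) and Tsga8 (1.83), Pcdhga4 (1.76), Alpk3 (1.65) and the glycine receptor gene Glrb (1.54). Among the largest falls, the protease gene Prss39 was at least 264-fold lower, Ccdc178 at least 196-fold, Ccdc7b at least 96.8-fold and Ccdc7a at least 93.1-fold, each with 0 counts over the 3 knockout libraries. The axonemal gene Nme8, with 2 knockout counts, was lower by a ratio of 329 (95% counting interval 90.7 to 2723), D6Ertd474e with 1 count by 267 (47.5 to 10590), Galntl6 with 2 counts by 195 (53.6 to 1616) and Ifitm7 with 2 counts by 172 (47.4 to 1429). Abca15 fell by 7.33 on the log2 scale. Predicted or clone-named models made up 25 of the higher and 360 of the lower genes.

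The number of genes changed at P18 fell to 1775 without wild-type library 8 and to 1757 without knockout library 12, and with a 2-fold minimum it was 1378. Without knockout library 12, Alpk3 (adjusted p = 0.0631), Glrb (0.101) and Tsga8 (0.0509) were not called. Glrb at P18 was also not called without wild-type library 8 (0.107) or knockout library 10 (0.0783), nor was Igf1 without wild-type library 8 (0.0983) or knockout library 12 (0.0979). Scaling by library totals alone, which moved the median log2 fold change of all genes from -0.00 to 0.12, gave 1694 higher and 2012 lower genes, a share of 45.7% higher against 17.5%. Groups did not overlap for 38.2% of genes, where chance gives 10%.

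At P28, when wild-type testes hold round and elongating spermatids, transcripts of spermatids were almost absent from the knockout and those of somatic cells were relatively more abundant. Of 47 elongating spermatid genes 46 fell and 1 rose, also adjusted over the list alone, with a median log2 fold change of -8.34 (quartiles -8.88 to -5.80). Prm1, a protamine that packs sperm DNA, fell from 4187 ± 1202 to 13.3 ± 18.5 CPM, and Tnp1, a transition protein, from 1740 ± 277 to 4.46 ± 6.42. Of 43 round spermatid genes 42 fell and none rose (42 fell and 1 rose adjusted over the list alone; median -6.92, quartiles -8.19 to -4.05). The acrosomal gene Acrv1 fell by 7.65 and Izumo1, needed for sperm and egg to fuse, by 6.92. All 42 tested axoneme genes fell (median -3.07), among them Tekt2 (-6.36) and Dnaic2 (-7.12). The camera adjusted p was 8.26e-15, 2.77e-14 and 2.76e-14 for these 3 lists, and with an estimated correlation the adjusted p = 0.503 for each.

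Genes of late meiosis stayed lower at P28 while those of earlier prophase stood higher. Of 39 pachytene genes 31 fell and 2 rose, also adjusted over the list alone (median -2.35, camera adjusted p = 1.78e-07; adjusted p = 0.503 with an estimated correlation). Ccna1 fell from 205 ± 53.3 to 3.02 ± 0.578 CPM, Pgk2, the germ-cell phosphoglycerate kinase, by 6.55 and Hspa2 by 1.33. Of 35 division genes 22 fell and 5 rose (24 and 5 adjusted over the list alone; median -0.96, camera adjusted p = 0.01; adjusted p = 0.716 with an estimated correlation), with the kinase genes Plk1 (-3.18), Aurkc (-3.29) and Aurka (-2.41) lower. Of 50 synapsis genes 25 rose and 9 fell (26 and 9 adjusted over the list alone; median 0.64, camera adjusted p = 0.0314; adjusted p = 0.660 with an estimated correlation). Mcmdc2 rose by 1.46 and Sycp3 by 0.86 (adjusted p = 0.0190), whereas the meiotic cohesin gene Rec8 fell by 3.12. The list synapsis and recombination at P28 was not called without wild-type library 3 (adjusted p = 0.0681), nor was Sycp3 at P28 without wild-type library 2 or knockout library 6 (adjusted p = 0.0751 and 0.0604).

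Among 32 piRNA pathway genes at P28, 3 rose and 8 fell (2 and 8 adjusted over the list alone), with a median of 0.05 and a mean of -0.29 (camera adjusted p = 0.956). Tdrd6 fell by 3.20, Gtsf1 by 3.03 and Ddx25, a helicase of spermatids and late spermatocytes, by 2.45. Piwil1 and Mybl1 stood at 0.03 and -0.01 (adjusted p = 0.897 and 0.975), and with library totals alone at 0.57 (0.0121) and 0.56 (0.0182). Of 38 spermatogonial genes 9 rose and 7 fell (8 and 7 adjusted over the list alone; median 0.49, mean -0.16, camera adjusted p = 0.251), and Dmrtb1 fell by 4.35.

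Most Leydig, Sertoli, peritubular and macrophage markers were higher at P28, and most endothelial markers were not called. Of 23 Leydig cell markers 19 rose and none fell (21 adjusted over the list alone; median 1.44), and the hormone gene Insl3 rose from 1556 ± 336 to 5509 ± 880 CPM. Of 36 Sertoli cell markers 28 rose and none fell (30 adjusted over the list alone; median 0.90), with Shbg rising by 2.20. Of 22 peritubular markers 13 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.81), and of 24 macrophage and immune markers 15 rose and 2 fell (18 and 2; median 1.23), including the lysozyme gene Lyz2 (1.78). The exceptions Actg2, a smooth muscle actin, and Aif1, a macrophage marker, fell by 5.24 and 6.50. Of 16 endothelial markers 5 rose and 2 fell (2 and 1 adjusted over the list alone; median 0.52, camera adjusted p = 0.0960). Camera adjusted p was 4.33e-06 for Leydig, 8.60e-07 for Sertoli, 0.00353 for peritubular and 0.00116 for macrophage markers. With an estimated correlation the adjusted p = 0.503, 0.503, 0.660 and 0.503.

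Sex-linked genes split at P28. Of 35 genes normally silenced at pachytene 25 rose and 1 fell, also adjusted over the list alone (median 0.90, camera adjusted p = 1.55e-05; adjusted p = 0.514 with an estimated correlation), with Zfx rising by 1.13. The member that fell, Tex13a (-8.13), is a testis-specific gene. Of 22 post-meiotic sex-chromosome genes 15 fell and 1 rose, also adjusted over the list alone (median -6.76, camera adjusted p = 3.23e-04; adjusted p = 0.503 with an estimated correlation). This list holds 2 autosomal members, Ccdc7b on chromosome 8 and Cypt4 on chromosome 9, and both are among the 15 that fell (-9.18 and -10.17). The Y-linked Sly, a regulator of sex-linked genes in spermatids, fell from 414 ± 229 to 3.69 ± 1.56 CPM. Of 719 X-linked genes 339 rose and 156 fell (353 and 156 adjusted over the list alone; median 0.83, mean -0.56, camera adjusted p = 5.28e-04 for a shift upward; adjusted p = 0.537 with an estimated correlation). Of 43 Y-linked genes 9 rose and 27 fell, also adjusted over the list alone (median -6.12, camera adjusted p = 0.00153; adjusted p = 0.503 with an estimated correlation). Zfy1 and Zfy2, higher at P18, stood at 0.21 and 0.12 (adjusted p = 0.502 and 0.657), and with library totals alone Zfy2 was called at 0.66 (0.0427).

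**Figure D2:**
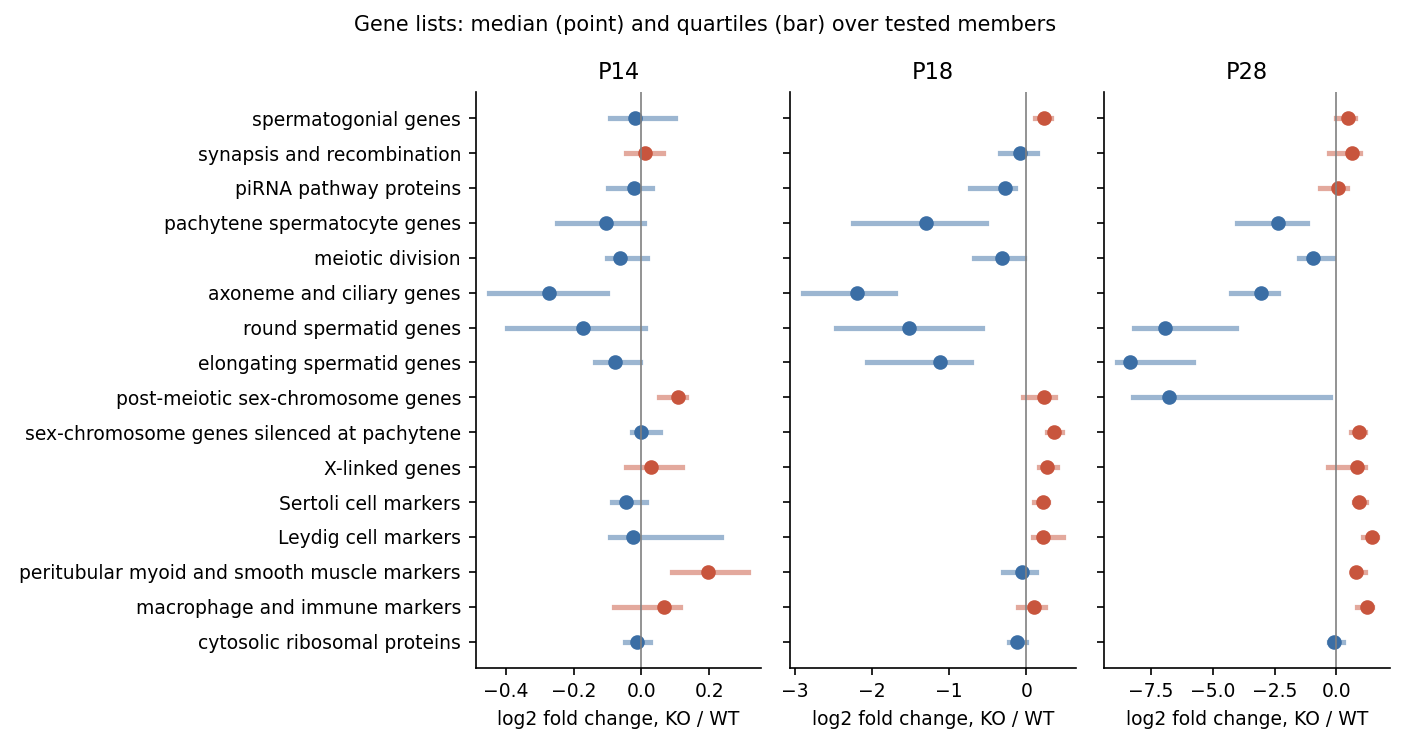
Median log2 fold change, knockout over wild type (points), and quartiles (bars) of 16 gene lists at P14, P18 and P28, with 3 libraries per genotype and age. Axoneme genes had medians of -0.27, -2.20 and -3.07, and Sertoli cell markers of -0.05, 0.21 and 0.90.

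In all, edgeR called 4347 of 17636 tested genes higher and 5578 lower at P28, or 56.3%, with 2369 and 4690 of them changed at least 2-fold. DESeq2 called 4306 higher and 6203 lower, and 9660 genes were called by both. The largest rises were those of the growth factor gene Fgf9 (5.01 ± 1.05), Ly6d (4.97), Myoz3 (4.73), the homeobox gene Nkx2-1 (4.44), Usp17la (4.16), the leukocyte integrin gene Itgax (3.84), Clca3a2 (3.77), Fos (3.53), the metalloproteinase inhibitor gene Timp1 (3.52) and Dsc2 (3.44). The 10 largest falls were of genes with 0 counts over the 3 knockout libraries. The thioesterase gene Acot10 was at least 993-fold lower, Zdhhc11 at least 884-fold, Abhd16b at least 804-fold, Iqcf6 at least 694-fold, Vmn2r7 at least 638-fold, Ccdc34os at least 606-fold, Slfn5os at least 422-fold, Cldn34d at least 412-fold, Rbm31y at least 406-fold and Samt2 at least 381-fold. Such zeros occurred for 230 of the called genes, against 7 at P18.

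Ly6d at P28 was not called without wild-type library 2 (adjusted p = 0.0609), nor was Fos at P28 without wild-type library 3 (0.0540) or knockout library 4 (0.0625). Scaling changed the balance at P28: with library totals alone the median log2 fold change of all genes moved from 0.05 to 0.59, and among genes changed at P28 7276 were called higher and 4252 lower, a share of 63.1% higher against 43.8%. Of the 9925 genes called, 100 had the opposite sign under that scaling, so values of genes near 0 at this age are relative to the scale. Groups did not overlap for 68.5% of genes, where chance gives 10%.

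Across ages, genes that fell at P18 also tended to fall at P28. Of the 15460 genes tested at both ages, 1984 fell at both, where independent lists would share 617, and 295 rose at both, where 134 would be shared. With a 2-fold minimum the genes changed at more than one age were 1149 that fell and 10 that rose. By the test of the difference itself, the genotype effect differed between P14 and P18 for 2279 of 16355 genes, with 441 more positive and 1838 more negative at P18. Ccna1 (-4.16, adjusted p = 4.48e-04), Tdrd6 (-2.44, 0.00299) and Ldhc (-1.89, 0.00430) were among the latter, and Zfy1 (1.26, 0.00326) and Zfy2 (1.54, 0.00382) among the former. Between P18 and P28 it differed for 4020 of 17773 genes (981 more positive and 3039 more negative). The changes of Zfy1 (-1.03, adjusted p = 0.0424) and Zfy2 (-1.42, 0.0106) were more negative at P28, and that of Piwil1 was more positive (1.09, 0.0104). The genotype effect differing between P14 and P18 was called for 1501 or 1490 genes without P14 wild-type library 1 or 3. The genotype effect differing between P18 and P28 was called for 6283 without P28 wild-type library 3, and 7048 with library totals alone, with 5122 more positive and 1926 more negative.

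The small RNA comparison asked how piRNAs of each genomic cluster change without D1PAS1. Values are the authors' normalized abundances. The 467 listed transcripts belong to 215 clusters, and each cluster is represented by its transcript with the highest mean over all libraries. Sums and shares below rest on these transcripts alone. Of the clusters 114 carry the name of a gene (genic) and 101 that of a chromosome band (intergenic). Intergenic clusters, which gave most of the signal, were lower in the knockout, and genic clusters were higher. The summed abundance of intergenic clusters was 512276 ± 48203 in wild type and 397931 ± 26109 in knockout, or 77.7% of wild type. Genic clusters summed to 30007 ± 8166 and 43968 ± 6226, or 147%. The total was 542282 ± 40186 against 441900 ± 20022, or 81.5%, and every knockout library lay below every wild-type library. The exact two-sided permutation p was 0.1 for the total and for intergenic clusters, the smallest that 3 against 3 samples allow, and 0.200 for genic clusters.

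Per cluster, limma called 66 clusters higher and 82 lower, or 148 of 215, with 165 at an unadjusted p under 0.05. Of the intergenic clusters 73 fell and 5 rose, with a median log2 fold change of -0.70 (quartiles -1.27 to -0.29). Of the genic clusters 61 rose and 9 fell, with a median of 1.29 (0.50 to 1.56). Values were below 0 for 89.1% of intergenic and 13.2% of genic clusters (Fisher's exact test over clusters, which are not independent samples, two-sided p = 1.31e-31). The class difference of -1.99 ranged from -1.52 to -2.55 when each library was left out.

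Clusters are named here by chromosome band, meaning the most abundant cluster of the band unless a further number is given. Among the clusters most abundant in wild type, 18-qE1 fell from 31264 ± 6258 to 12337 ± 1641 (log2 fold change -1.33 ± 0.17, adjusted p = 0.00284), 9-qA5.3 by 1.19 and 6-qF3 by 0.64. The most abundant of all, 17-qA3.3, stood at 52699 ± 1809 and 58511 ± 984 (0.15 ± 0.05, adjusted p = 0.0491, not called without any of the libraries, 0.0564 to 0.145), and the second most abundant cluster of that band rose by 0.48. The cluster 9-qC-31469 stood at -0.19 (adjusted p = 0.0683), 2-qE1 at -0.17 (0.0555) and 7-qD2 at -0.17 (0.111). The second cluster of 7-qD2, 9-qC-10667 and 6-qF3-8009 fell by 0.71, 0.49 and 0.43. The largest falls were those of pi-Arhgap20 (-3.72), 8-qA4-332 (-3.06), 3-qA2-617 (-3.0), 8-qA4-155 (-2.76) and 4-qD2.2 (-2.71). The largest rises were those of pi-Hjurp (2.17), pi-Rplp1 (1.93), 1-qE2.3-2 (1.86), pi-Zfp866 (1.85) and pi-Zyg11a (1.82).

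Calls of single clusters depended on the libraries used. Without wild-type library 1, 2 or 3, the numbers called were 28, 38 and 197, and without knockout library 1, 2 or 3 they were 66, 38 and 36. The calls of higher clusters were 1, 1, 100, 3, 1 and 1 in the same order. The rise of the second cluster of 17-qA3.3 was called without each library (adjusted p up to 0.0245), while the 5 largest rises were not called without wild-type library 1 or 2 or knockout library 2 or 3 (0.0543 to 0.154), nor were pi-Rplp1, pi-Zfp866 and pi-Zyg11a without knockout library 1 (0.0542 to 0.0668). The cluster 8-qA4-155 was not called without wild-type library 1 (adjusted p = 0.0530). The cluster 6-qF3-8009 ranged from 0.0548 to 0.0832 without wild-type library 1 or 2 or knockout library 2 or 3, and cluster 9-qC-10667 from 0.0645 to 0.0832 without the same libraries. Genic clusters made up 4.70%, 4.27% and 7.91% of the abundance in the wild-type libraries and 8.16%, 11.8% and 10% in the knockout libraries. With every library scaled to the same total 89 clusters were called higher and 62 lower, against 66 and 82, and 9-qC-31469 and 2-qE1 were then called higher (0.10 and 0.12).

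**Figure D3:**
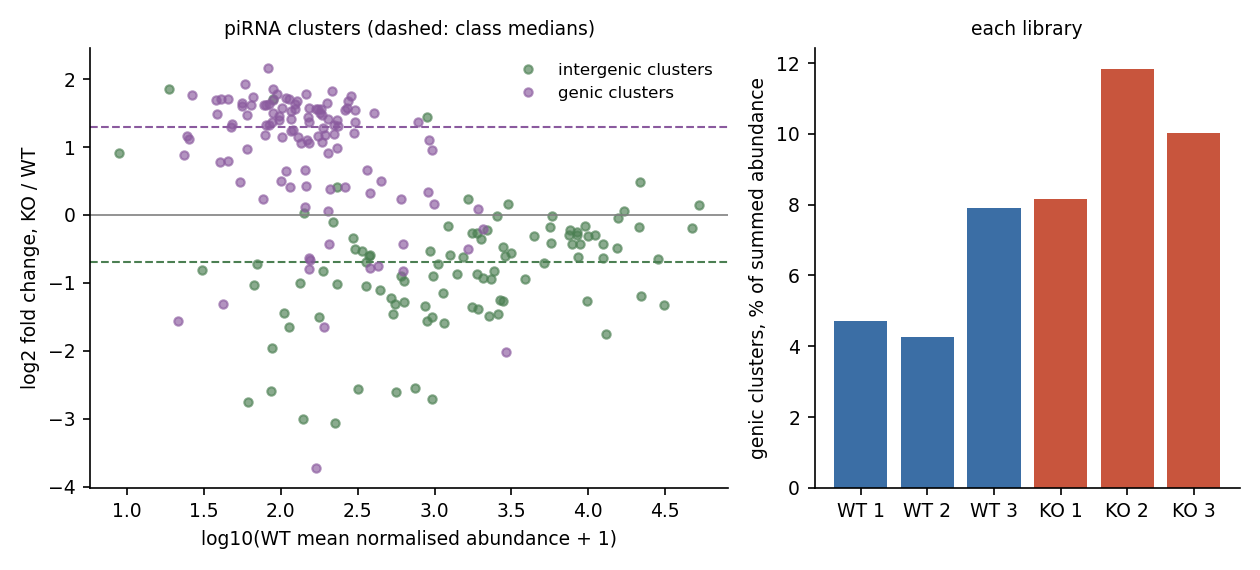
Left, log2 fold change (knockout over wild type) of each piRNA cluster against its mean wild-type abundance (log10), with class medians of -0.70 for intergenic and 1.29 for genic clusters as dashed lines. Right, the percentage of summed abundance in genic clusters in each library, from 4.27% in wild type 2 to 11.8% in knockout 2.

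The eCLIP comparison asked which RNAs are enriched with D1PAS1 over the size-matched input. Counts used per library were 262049, 2741420 and 3665538 in the inputs and 144662, 138887 and 102257 in the IPs. Counted over exon and intron windows together, 32 of 41 tested intergenic piRNA clusters (78.0%) were enriched and 1 was depleted, with a median log2 fold change of 2.18, against 616 of 4939 genes (12.5%) enriched and 418 depleted. The odds ratio was 24.9 (95% interval 11.6 to 59.7; Fisher's exact test over features, two-sided p = 2.55e-21). The share of 78.0% holds for clusters that passed the low-count filter, which a feature can pass through its IP counts alone. Without the filter 40 of 101 intergenic clusters (39.6%, median 1.00) and 951 of 42477 genes (2.24%) were enriched. By DESeq2 it was 36 of 93 intergenic clusters (38.7%) and 926 of 19313 genes (4.79%). From exon windows alone, an alternative chosen after seeing the data, the contrast was not detected: 17 of 35 intergenic clusters (48.6%) and 152 of 404 genes (37.6%) were enriched (odds ratio 1.56, 0.733 to 3.33, p = 0.210 by the same exact test), with medians of 0.85 and -0.68. Without IP library 3, 20 of 49 intergenic clusters were enriched (40.8%) and 559 of 6987 genes (odds ratio 7.93). Of 33 genic clusters 6 (18.2%) were enriched, a share that was not detectably different from that of genes (p = 0.294 by the same exact test), and the classes of clusters differed from each other (p = 4.07e-07 by the same exact test). From exon windows alone 17 of 35 intergenic and 0 of 3 genic clusters were enriched, and from intron windows alone 0 of 3 and 4 of 24. Too few clusters of 1 class were thus tested to compare the classes over like windows. Over both kinds of windows, the 11 clusters that had been named for the small RNA data by abundance or by name were enriched. From exon windows alone 3 of them were not called: 6-qF3-8009 (0.30, adjusted p = 0.438), 9-qA5.3 (0.48, 0.368) and the second cluster of 17-qA3.3 (0.85, 0.0918). Without IP library 3, 5 of the 11 were not called, namely these 3, the second cluster of 7-qD2 and 9-qC-10667 (adjusted p = 0.0594 to 0.0768). Without IP library 1 the second clusters of 7-qD2 (0.0662) and 17-qA3.3 (0.0508) and 9-qA5.3 (0.0618) were not called, nor was 9-qA5.3 without input library 2 (0.0552). Of the clusters with the largest falls in small RNA, the 2 tested were not called (pi-Arhgap20 0.30, adjusted p = 0.542; 3-qA2-617 0.22, 0.727), but from exon windows alone 3-qA2-617 was depleted (-1.52, adjusted p = 6.83e-04). The enriched clusters included 18-qE1 (93.8 ± 41.3 CPM in input, 1017 ± 615 in IP; log2 fold change 3.33, adjusted p = 0.00155), 6-qF3 (2.98), 17-qA3.3 (2.67) and 2-qE1 (2.54). Clusters held 0.854 ± 0.125% of input and 1.78 ± 0.731% of IP counts (exact two-sided permutation p = 0.1, the smallest possible).

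In all, edgeR called 654 of 5013 tested genes and clusters enriched and 420 depleted, with 245 enriched at least 4-fold. DESeq2 called 967 and 542, and 464 were enriched by both tools. Without IP library 1, 2 or 3 the enriched features numbered 523, 654 and 583, and the depleted ones 134, 159 and 140. Of the 420 depleted features 106, 119 and 109 were kept in these fits. Without the low-count filter 1737 were depleted. The largest enrichments were those of the predicted genes Gm47294 and Gm22701, for which the coordinates are not known here. Gm47294 had 2 input and 78 IP counts, a ratio of 769 (95% counting interval 206 to 6459), and Gm22701 had a log2 fold change of 8.23. Next came Gm11658 (7.78), Cdk5r2 (6.85), Slc16a6 (6.73), the lipid transporter gene Abca8b (6.55), Oaz1 (6.55), which encodes ornithine decarboxylase antizyme, Fam20a (6.53), 1700012B07Rik (6.37) and E030025P04Rik (6.36). Of these 10, Gm11658, Slc16a6, Abca8b, Fam20a, 1700012B07Rik and E030025P04Rik lie within 857 kb of chromosome 11 (109139291 to 109996274). D1Pas1 had 202 counts over the inputs and 21 over the IPs, Ddx3x 66 and 1, and Ddx3y 92 and 3, and none of them had enough counts to be tested. These are unscaled counts, and the inputs were deeper (262049 to 3665538 counts used per library, against 102257 to 144662 in the IPs). They therefore do not show enrichment or depletion.

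Germ-cell and translation genes were among those enriched. Of 9 tested translation factor genes 3 were enriched and none depleted (5 adjusted over the list alone; camera adjusted p = 0.142): Eif3c (log2 fold change 4.68), Eif3a (2.30) and the elongation factor gene Eef2 (2.79). Of 11 elongating spermatid genes 4 were enriched, also adjusted over the list alone, including Odf1 (3.36), Akap4 (2.10) and Tnp1 (1.91). Of 12 pachytene genes 3 were enriched, also adjusted over the list alone: Hspa2 (2.97), Ldhc (1.82) and Tesmin. Tdrd7 and Morc1 were enriched among 13 piRNA pathway genes (2 enriched, 3 and 1 depleted adjusted over the list alone). These members were chosen after their values were seen. No list differed from the other genes by camera, where 14 lists were tested, and the lowest adjusted p was 0.142. The list translation factors and regulators in eCLIP was called without input library 1 or 2, or IP library 2 (adjusted p = 0.0417, 0.00218 and 0.0484), and the list elongating spermatid genes in eCLIP without input library 1 or 2 (0.0250 and 0.00124).

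Counts in all eCLIP libraries rose with gene length. Across 16168 genes, which are not independent, Spearman's rho with length was 0.704 to 0.867 per library, and with wild-type RNA at P28 it was 0.140 to 0.240. Windows in exons held 19 ± 1.52% of input and 23.6 ± 3.64% of IP counts (exact two-sided permutation p = 0.200). From exon windows alone 169 features were enriched and 200 depleted, and from intron windows alone 422 and 295. The number of enriched clusters, 38 of 74 tested, was 24 of 102 tested without IP library 3. With library totals alone 543 features were enriched and 726 depleted, a share of 42.8% enriched against 60.9%, and the median log2 fold change moved from 0.01 to -0.14. Groups did not overlap for 43.6% of features, where chance gives 10%.

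**Figure D4:**
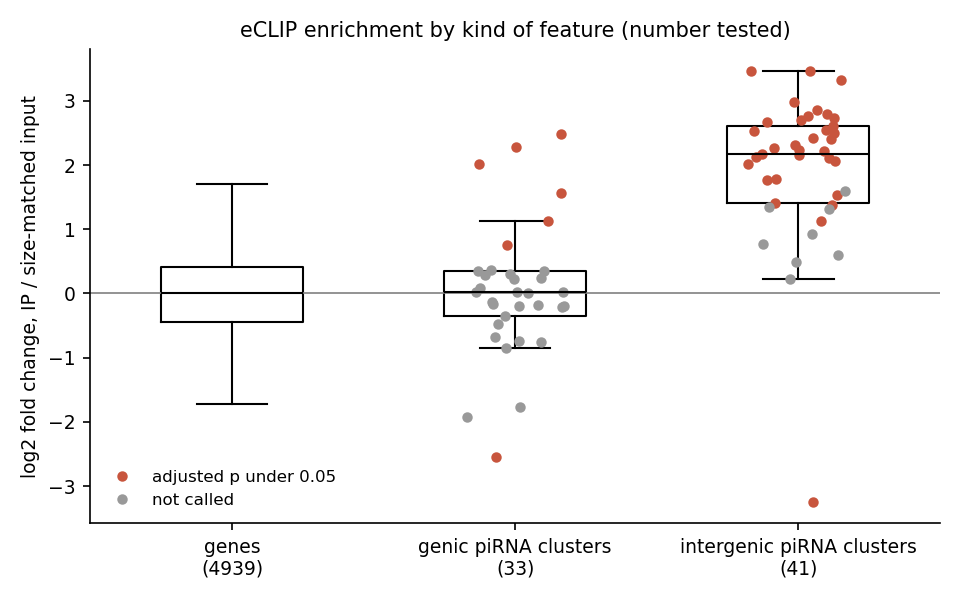
Log2 fold change over exon and intron windows, IP over size-matched input, of 4939 genes (box: median and quartiles), 33 genic and 41 intergenic piRNA clusters (box and points; filled colour for adjusted p under 0.05). The median was 0.00 for genes, 0.03 for genic and 2.18 for intergenic clusters.

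The enriched genes on chromosome 11 formed a run. Between 109139291 and 109996274 (GRCm38), 8 genes whose windows are numbered in descending order of exon number had log2 fold changes of 6.04 to 6.73: E030025P04Rik, Rgs9, Gm11696, Slc16a6, Wipi1, Fam20a, 1700012B07Rik and Abca8b. Together they held 2.63% of IP and 0.0359% of input counts, a ratio of 73.4 (95% counting interval 70.2 to 76.8). The 6 genes between them with ascending order, Gna13, Amz2, Arsg, Gm11685, Prkar1a and Gm11683, had a pooled ratio of 0.562 (0.444 to 0.704), to which Arsg gave most input counts (273 CPM in input, 78.8 in IP). Prkar1a (12.7 and 34.4 CPM) and Gm11683 (2.31 and 11.7 CPM) stood higher in the IP, with few counts. The neighbours Abca9 and Abca5 just beyond the run stood at 0.35 (adjusted p = 0.466) and -0.30 (0.689). This run and its genes, apart from the largest enrichments, were singled out after their values were seen. Counting intervals here cover counting error alone, and the counted events need not be independent molecules.

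**Figure D5:**
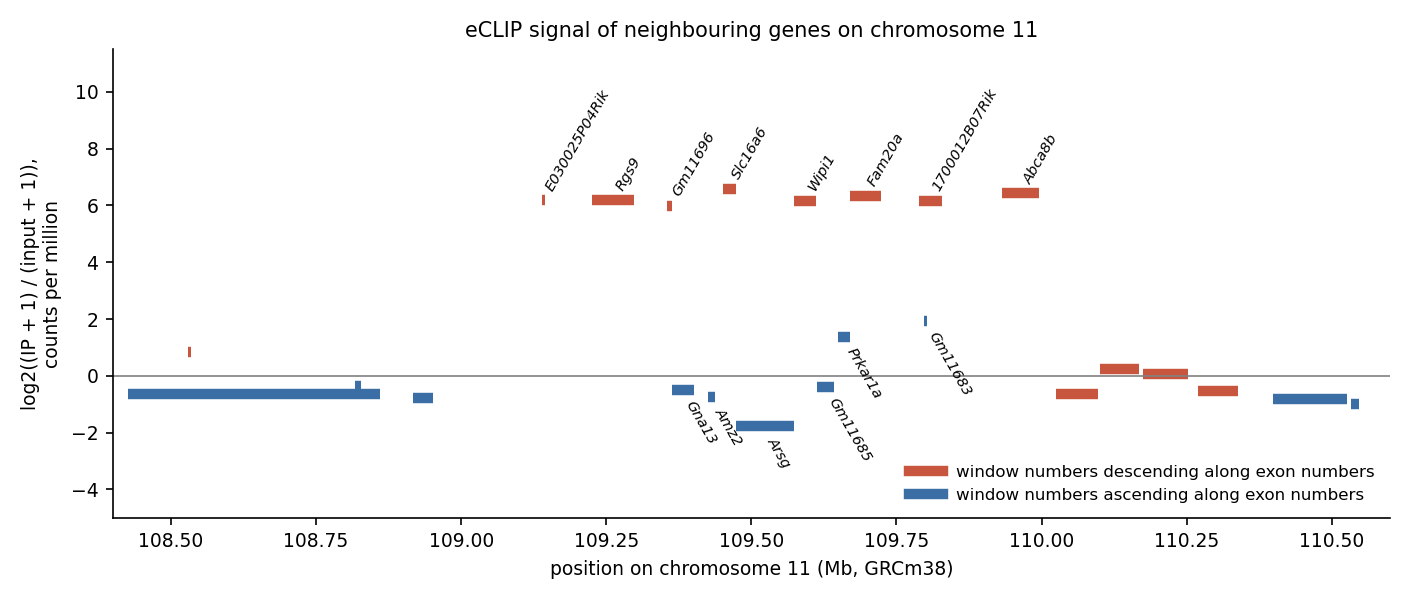
Log2 ratio of IP to input (pooled CPM plus 1) of genes on chromosome 11 (position in Mb, GRCm38), coloured by whether window numbers descend or ascend along the exon numbers of the gene. The 8 descending genes of the run reached log2 fold changes of 6.04 to 6.73, and the ascending genes among them had a pooled ratio of 0.562.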

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

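The tests of cell stage, of scaling, of normalization, of wild-type library 3, of extra copies and of DNA in the precipitates were chosen only after the result was seen. The counts of other splits of the samples were planned.

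The genotype effect differed between ages by a test of the difference itself, which is why these results are set apart. The genotype effect differing between P14 and P18 was called for 2279 genes by edgeR. The genotype effect differing between P18 and P28 was called for 4020 genes. In 40 drawn splits of the libraries within each age, the real one included, 3 gave as many genes for P14 and P18 (highest other split 2959) and 4 for P18 and P28 (highest other 7178), so chance is not excluded by these counts. All of these splits kept the genotype groups of the later age whole, as 5 and 4 of the 40 did. Such splits still hold the genotype difference of that age, so they cannot decide about chance. The highest count with the later groups mixed was 1 for the first comparison and 0 for the second.

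Of the genes that rose at P18, 40 fell at P28, and 6 went the other way, each with a called difference between the ages. Independent lists would share 128 and 647. Of these 46 genes 3 are named by the rule, all X-linked. For 1700080O16Rik and Gm9 this follows from the rule, which names clone-named genes only as members of a list, here that of X-linked genes. The chromosomes of the other genes are not given here, so no link of such reversals to the X chromosome is shown. Tsga8, a testis-specific gene, rose at P18 from 7.22 ± 4.15 to 25.6 ± 4.79 CPM (log2 fold change 1.83) and fell at P28 from 87.1 ± 31.3 to 13.7 ± 3.09 (-2.67), a difference of -4.66 ± 0.57 (edgeR, adjusted p = 1.16e-04). Tsga8 at P18 was not called without knockout library 12 (adjusted p = 0.0509). The clone-named 1700080O16Rik went from 1.63 at P18 to -0.81 at P28, a difference of -2.59 ± 0.33 (adjusted p = 1.65e-04), and Gm9 from 2.52 to -1.28, a difference of -3.96 ± 0.43 (adjusted p = 5.02e-05). Every knockout library lay beyond every wild-type library at both ages for these 3 genes.

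The first pattern weighed is that late meiotic and spermatid genes were lower at P18 while X-linked genes were higher. Of the 2354 genes lower at P18 and tested in wild type, 91.1% (95% interval 89.9 to 92.2) rise in wild-type testes from P14 to P28, against 24.2% of genes not called, so a smaller share of cells of the later stages may account for falls such as those of Ccna1, Ldhc and Tekt3. The 2 ages come from different tables, so a batch between them is part of that comparison. X-linked genes exceeded autosomal genes of like level and like change from P14 to P28 by a median of 0.16 (0.15 to 0.19). That match cannot decide whether a smaller share of later cells also raises X-linked genes. A change from P14 to P28 need not follow the level in pachytene spermatocytes, where such genes are normally silenced. Intervals in this paragraph treat genes as independent units and leave out the spread between samples. A scaling factor was not tested by comparing scalings, because it moves X-linked and autosomal genes alike: the gap between their medians was 0.29 with TMM and 0.29 (0.27 to 0.30) with library totals alone, by construction. A factor cannot make that gap, but how far X-linked genes lie above 0 depends on the scale. What remains open for the X-linked genes is a smaller share of cells of the later stages or an excess of cells of a stage with more X-linked transcripts. A change of X-linked transcription within spermatocytes, as the rise of Zfy1 and Zfy2 could also reflect, is open too, and no test here separates them.

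The second pattern is that genic piRNA clusters were higher and intergenic clusters lower in the knockout. A single normalization factor moves both classes alike, so the gap of 1.99 between their medians cannot come from it. Whether the 2 classes lie on opposite sides of 0 does depend on that factor, and no value here settles it. With every library scaled to the same total the medians were 1.58 (95% interval 1.42 to 1.68) for genic and -0.41 (-0.61 to -0.27) for intergenic clusters, but a fixed total forces the classes to balance. These intervals come from resampling clusters, which are not independent, and leave out the spread between samples. A make-up or stage of the sampled testes that varies within a genotype may account for the gap. Across clusters the difference of wild-type library 3 from library 1 followed that of the knockout mean from wild-type library 2 (r = 0.955; 0.933 in genic and 0.877 in intergenic clusters alone). Projected over all clusters, wild-type library 3 lay 65.9% of the way from the other wild-type libraries to the knockout mean. By the same measure wild-type libraries 1 and 2 lay at -23.6% and -66.1%. The baseline for each was the mean of the other wild-type libraries, library 3 included. These negative values thus follow in part from the shift of library 3 and do not show a departure of their own. A direct effect of D1PAS1 on precursors of intergenic clusters stays open, and the ages of these samples are not given.

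The third pattern is the run of enriched genes on chromosome 11, from E030025P04Rik to Abca8b. Extra copies of the region as the whole cause are argued against: input counts per kb were 1.61 times those of other genes of the chromosome (1.39 to 1.98), while the precipitates were raised 129 times. The criterion of this test was rewritten after a first form, which used the input alone, could not decide. DNA in the precipitates as the whole cause is argued against by the 6 genes of the other reading direction, with a pooled ratio of 0.562 (0.444 to 0.704) against 73.4 for the 8 genes of the run. Arsg dominates that pool, and Prkar1a (12.7 CPM in input, 34.4 in IP) and Gm11683 (2.31 and 11.7) were higher in the IP, far less so than the run. The reading direction of Gm11658 (3.0 CPM in input, 196 in IP) and 1700096J18Rik (4.46 and 35.0), which also lie in the run and were higher in the IP, is not known, so their rise would follow from DNA and from a transcript on 1 strand alike. A transcript that runs through the region on 1 strand in the knock-in testes may be the source, whether bound by the protein or linked to the construct, and no biological explanation was tested. No other 1 Mb stretch held more than 3 genes enriched at least 8-fold, against 9 here.

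For comparisons of 3 against 3 samples the 10 possible splits are too few for a share under 0.05. The real split gave 0 genes at P14, and all 10 splits gave as many (highest other 10). At P18 1 of 10 splits, the real one, gave as many as 2867 genes (highest other 0), and at P28 1 of 10 gave as many as 9925 (highest other 0). As many gene lists as the real 5, 13 and 16 were called in 10, 6 and 2 of the 10 splits at P14, P18 and P28, with 13, 14 and 17 as the highest other. For piRNA clusters it was 1 of 10 (real 148, highest other 0) and for eCLIP features 1 of 10 (real 1074, highest other 0). For gene lists in eCLIP, where 0 were called, it was 10 of 10 (highest other 4). Since other splits called as many lists, camera with the preset correlation does not by itself tie a list to genotype at any of these ages.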

How the results depend on the processing

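Of the alternatives, those that use every small RNA transcript as its own unit, other eCLIP windows, exon windows alone or intron windows alone were chosen after seeing the data, and the others were planned. Where a result changed, the cause was not tested unless stated. Of the counts and totals under an alternative, 119 stayed within 1.5 times their value or within the spread of replicates, and 29 did not. Of values of named genes and clusters, 4050 kept their side of the threshold, 53 passed it newly, 113 no longer passed it and 3 reversed. For gene lists these numbers were 671, 30, 43 and 2. Direction was compared only where a value passed the threshold in the main fit or under the alternative. A change of sign between values that were not called in either therefore counts as kept. Of the losses among named genes and clusters, 100 came from leaving out 1 library.

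The number of genes changed at P14 was 0 by edgeR (948 at an unadjusted p under 0.05), 58 by DESeq2, 4 without the low-count filter, and from 0 without wild-type library 1 to 11 without wild-type library 2. The number of genes changed at P18 was 2867, and 1378 with a 2-fold minimum, which counts fewer genes by construction, and from 1757 (without knockout library 12) to 3319 (without wild-type library 9). The number of genes changed at P28 ran from 7122 to 10270 when a library was left out. The genotype effect differing between P14 and P18 was called for 1490 (without P14 wild-type library 3) to 3104 genes (without P18 wild-type library 9). The genotype effect differing between P18 and P28 was called for 2805 (without P18 knockout library 12) to 6283 (without P28 wild-type library 3), and for 7048 with library totals alone. The number of genes changed at more than one age was 1159 with a 2-fold minimum. Mybl1 at P28 reversed, to 0.56, with library totals alone.

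Gene lists changed at P14, P18 and P28 numbered 0, 0 and 0 with an estimated correlation. When a library was left out, gene lists changed at P14 numbered 4 (without knockout library 5) to 12 (without wild-type library 3). The list pachytene spermatocyte genes at P14 had an adjusted p from 1.78e-04 (without wild-type library 3) to 0.513 (without knockout library 5). The list elongating spermatid genes at P14 had one from 0.0391 to 0.841 for the same libraries. Without wild-type library 2 these lists were called in the opposite direction, higher (0.0240 and 0.0419).

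The piRNA clusters changed numbered 28 without wild-type library 1 and 197 without wild-type library 3, and with every listed transcript as its own unit 331 of 467 were called. With each library scaled to the same total, cluster 9-qC-31469 and the cluster of band 2-qE1 reversed, to 0.10 and 0.12. The eCLIP genes or regions enriched in IP over size-matched input numbered 997 without the low-count filter, 169 from exon windows and 422 from intron windows, which test fewer features by construction. Gene lists in eCLIP numbered from 0 (without input library 3) to 2 (without input library 1).

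No paired analysis was possible because the RNA-seq columns of the 2 genotypes share no numbers, so the planned replicate block was not run there. For small RNA the replicate block gave 127 clusters, 64 higher and 63 lower, and the most abundant cluster, of 17-qA3.3, was then not called (adjusted p = 0.165). For eCLIP the replicate block gave 588 enriched and 497 depleted features. Of the 38 enriched clusters 36 were kept, without pi-Eif2c2 (adjusted p = 0.0604) and 1 intergenic cluster (0.0573). The block changed no other call of the 21 clusters named for small RNA, and none of the 10 genes with the largest eCLIP enrichments or of the 11 clusters named in the eCLIP part as enriched. The deviations of samples with the same number correlated at 0.65, -0.89 and 0.40 in small RNA and at 0.02, -0.17 and -0.03 in eCLIP, so the numbers are not shown to pair samples. The alternatives for peaks were not run, since the eCLIP values are counts. Depth limits the precipitates, with 102257 to 144662 counts used.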

Other observations

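The tests of the 2 hypotheses below were planned. Genes named singly here follow the naming rule unless stated. Genes for processing R-loops and for DNA repair changed singly rather than as groups. Rnaseh2a, the catalytic subunit of the RNase H2 that cleaves RNA in RNA-DNA hybrids, fell at P18 (-1.90 ± 0.18, edgeR adjusted p = 1.62e-04) and at P28 (-3.86 ± 0.25, adjusted p = 1.65e-05). Of 44 tested R-loop genes 6 fell at P18 and none rose, also adjusted over the list alone (median -0.10, camera adjusted p = 0.205), among them Thoc5 (-0.69), Thoc7 (-0.80) and the helicase gene Rtel1 (-0.76). At P28 11 rose and 8 fell (10 and 6 adjusted over the list alone; median 0.07, mean -0.07, camera adjusted p = 0.465), with Thoc2 at 1.23 and Top3b at -0.99. Of 40 DNA repair genes 1 rose and 5 fell at P18, also adjusted over the list alone (median -0.08, adjusted p = 0.505), and 10 rose and 7 fell at P28 (10 and 6; median 0.23, adjusted p = 0.205). Xrcc1 and Rpa1 fell at both ages (-0.72 and -0.78, then -1.50 and -1.90), and Scml2, an X-linked regulator of silencing, rose at both (0.50 and 1.05). Of 32 p53 targets 3 rose at P18, also adjusted over the list alone (median 0.17, adjusted p = 0.0127; adjusted p = 0.503 with an estimated correlation), and at P28 17 rose and 3 fell (18 and 3; median 0.92, adjusted p = 5.99e-04; adjusted p = 0.503 with an estimated correlation). Sertoli and peritubular markers had medians of 0.90 and 0.81 in the same libraries, and no test compared the lists with each other. Ccng1 rose at both ages (0.58 and 1.24) and the apoptosis gene Perp at P28 (2.10), although Ccng1 at P18 was not called without wild-type library 8 (adjusted p = 0.0637) or knockout library 12 (0.0805).

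Germ-cell poly(A)-binding protein genes were among the strongest falls of the translation list. Pabpc2 fell by 4.38 and 4.91 and Pabpc6 by 3.33 and 4.01 at P18 and P28. Of 36 translation genes 2 rose and 6 fell at P18, also adjusted over the list alone (median -0.12, camera adjusted p = 0.290), and 5 rose and 18 fell at P28 (5 and 19; median -0.71, adjusted p = 0.0548). The list translation factors and regulators at P28 was called with RLE factors (0.0496) and without wild-type library 2 (0.0384) or 3 (0.0173) or knockout library 6 (0.0493). Interferon response genes rose at P28, where 17 of 25 rose and 2 fell (19 and 2 adjusted over the list alone; median 1.27, adjusted p = 0.00102; adjusted p = 0.503 with an estimated correlation), including Ifit1 (2.21) and Ifih1 (1.43), while Dhx58 fell by 3.23. Macrophage and immune markers had a median of 1.23 and Leydig markers of 1.44 in these libraries, and no test compared the lists. At P18 1 of 24 fell, Dhx58 (-3.17), and the median was -0.01 (adjusted p = 0.343). Ribosomal protein genes had medians of -0.12 and -0.09 over 63 genes at P18 and P28 (adjusted p = 0.447 and 0.745), with 0 called at P18 by edgeR (0 by the adjustment over the list alone) and 7 higher and 8 lower at P28 (3 and 4). The list cytosolic ribosomal proteins at P18 was called without knockout library 10 (0.00521), the list interferon response at P18 without wild-type library 8 (0.0304) and the list red blood cell genes at P18 without wild-type library 7 (0.0130). Red blood cell genes had medians of 0.92 over 6 genes at P18 and -0.29 over 7 at P28 (adjusted p = 0.112 and 0.680), with Bpgm (-2.05) and Alas2 (-1.36) lower at P28.

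At P14 the lists not described in the report had medians between -0.17, for 22 round spermatid genes (camera adjusted p = 0.0641), and 0.11, for 6 post-meiotic sex-linked genes (0.125), and none was called. Without wild-type library 2 or 3, lists of this group such as synapsis (the list synapsis and recombination at P14, 0.01) or round spermatid genes (the list round spermatid genes at P14, 2.35e-04) were called. Cyp17a1, of Leydig cells, stood at -0.50 (edgeR adjusted p = 0.860), 0.83 (0.274) and 1.44 (0.0125) at P14, P18 and P28, Sox9, of Sertoli cells, at -0.18 (0.717), 0.21 (0.247) and 0.76 (0.0142), and Stra8 at 0.27 (0.173) at P18 and 0.77 (0.0261) at P28. Without wild-type library 2, Cyp17a1 at P28 (adjusted p = 0.0552) and Sox9 at P28 (0.0614) were not called, and Stra8 at P28 was not called without any library other than wild type 3 (0.0566 to 0.102).

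The first hypothesis was that piRNA clusters bound more strongly by D1PAS1 lose more small RNA in the knockout. Over all 74 tested clusters Spearman's rho of eCLIP enrichment with small RNA change was -0.50 (permutation p = 2.00e-05, adjusted p = 6.00e-05). Within the 41 intergenic clusters it was 0.12 (permutation p = 0.468, adjusted p = 0.468), and within the 33 genic clusters -0.26 (permutation p = 0.152, adjusted p = 0.228), with 100000 two-sided permutations each. The negative value over all clusters therefore goes with the difference between the classes, and the data do not bear out a relation within intergenic clusters.

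The second hypothesis was that genes enriched in the precipitates fall more often at P18 than other genes of a like RNA level. Of 459 enriched genes 97 fell (21.1%), against 13.6% of the other genes among 3624 tested in both. The odds ratio over 10 strata of RNA level was 1.71 (95% interval 1.34 to 2.20, two-sided stratified test p = 2.50e-05), and for rises the shares were 3.27% and 4.45% (Fisher's exact two-sided p = 0.270). Bound RNAs may thus be lost more often, with the reservation that genes are not independent samples and that eCLIP counts follow gene length and the cell types that express a gene.

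In the second value column of the small RNA tables, whose meaning is not given in the sources used here, clusters summed to 448 ± 62.1 in wild type and 383 ± 20.1 in knockout (mean ± SD, n = 3 each). The cluster pi-Eif2c2 stood at 18.7 ± 4.71 and 2.72 ± 0.679, and pi-Zfp280b at 17.9 ± 1.58 and 10.1 ± 0.882. These clusters were singled out after their values were seen.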
